A study of Homo sapiens with 4 samples.

How the data were processed

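The series holds 4 two-colour Agilent gene expression arrays of LNCaP cells. Per the labels, cells were serum starved for 24 h and treated with 1 µM 5-azacytidine or DMSO for 24 h or 48 h, and total RNA was extracted with Trizol and labelled by reverse transcription. On each array the vehicle RNA was in Cy3 and the treated RNA in Cy5, with no dye swap. The array names in the labels carry one slide number, so slide was no batch to test. The arrays were grouped by time, with 2 replicates each.

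The authors deposited one table of log10 ratios with 45220 rows, of which 43376 features had a value on all arrays and 1844 were blank on all. Per the submitters' processing notes, the values came from Agilent Feature Extraction 8.5.1.1. Their settings were not given in the sources used here. The table states neither the base nor the direction of its values. They were read as log10 of Cy5 over Cy3, the software's convention, and multiplied by log2 of 10, so that base and direction rest on that convention and on the dyes in the labels. The column medians were 0 on each array, and the centring that gave them is not stated. The standard deviation of gene ratios was 0.915 and 0.954 on the 24 h arrays and 1.07 and 1.28 on the 48 h arrays. On each array between 6011 and 6695 features were listed at exactly 0, a value that the software writes for several reasons, including neither channel standing above background. Intensities were not analysed here, so no filter on signal or background could be set.

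Features were named from the platform annotation through gene identifiers of the gene table of assembly GRCh38.p14. Of 31425 annotated features, 31291 had an identifier in that table, and 0 symbols changed. Of the features with values, 31332 had 1 gene symbol, 93 had several and 11951 had none, and only those with 1 symbol entered the gene analysis. The mean over the features of a gene gave 18334 genes, 7759 of them with more than 1 feature. For 51 of these 7759 genes, features passed the threshold in opposite directions when tested singly in the average over both times. Such genes were not counted at the single times. All 4 values were listed at 0 for 1089 genes.

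Gene ratios were fitted with limma 3.58.1 in R 4.3.3, with one mean per time over all 4 arrays and moderated variances, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. The tests were of each time against 0, of the average of both times and of 48 h minus 24 h. The fit had 2 residual degrees of freedom and 0.735 prior degrees of freedom. Gene lists, 21 with 537 measured genes, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Camera with an estimated correlation has no more than the 2 residual degrees of freedom of the fit, and thus little power here. The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, at each time, the 10 genes with the highest and the 10 with the lowest mean ratio among those past the threshold with both arrays of one sign, for the difference the 5 highest and 5 lowest whose arrays did not overlap between times, from each list the 4 members with the lowest p in the average, and 6 genes set in advance, of which 5 were analysed here.

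The fit was tested on simulated data for 18334 genes, drawn independently with each gene's spread pooled over the 4 arrays. Both times thus had the same spread, whereas the median absolute difference between replicate arrays was 0.126 at 24 h and 0.332 at 48 h. The rates below hold for that setting and are not error rates of the real calls. With 200 genes changed, it recovered 52% of those changed by 3 on the log2 scale at 24 h, 50% at 48 h, 72% in the average and 0% in the difference. With 6000 changed, it recovered 65.7%, 64.7%, 80.7% and 50.9% of those changed by 1, in the same order, and between 4.40% and 4.99% of calls were of unchanged genes. Among unchanged genes of the first simulation between 6.65% and 7.10% had an unadjusted p under 0.05, so that counts at that level were somewhat too high there and may be so in the real data. The precision of every value is limited by the number of arrays.

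The alternatives were a replicate block, centring, scaling and quantile normalization of the arrays, the median of a gene's features, features in place of genes, removal of features with an exact 0, robust variance moderation, a 2-fold size threshold, the values read as log2, the arrays of one time only, other list tests and each array left out in turn. Others were chosen after seeing the data, namely the averaging of features of one accession first, the removal of genes at 0 on all arrays, and that removal together with each array left out. A planned comparison of disagreeing features with spot noise was not run. Figures were drawn with matplotlib 3.10.9.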

Results

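LNCaP cells, an androgen-responsive line grown from a lymph node metastasis of a human prostate carcinoma, were deprived of serum for 24 h and then given 1 µM 5-azacytidine or its vehicle, dimethyl sulphoxide (DMSO), for 24 h or 48 h. 5-azacytidine is a cytidine analogue that is built into nucleic acids, traps DNA methyltransferases and lowers DNA methylation in dividing cells. RNA from treated cells and from vehicle cells of the same time was hybridised together on 2-colour Agilent arrays, 2 arrays at 24 h and 2 at 48 h, so that each array gave the ratio of treated to vehicle cells for 43376 features. Those with a single gene symbol, 31332 in all, measured 18334 genes. Gene ratios correlated with r = 0.917 between the 24 h arrays and r = 0.873 between the 48 h arrays, and with r = 0.293 to 0.540 between arrays of different times, all across genes, which are not independent replicates. The median absolute difference between replicate arrays was 0.126 on the log2 scale at 24 h and 0.332 at 48 h. The number of arrays limits the precision of every value. Nothing in the labels says that replicates came from separate cultures, so limma p-values measure only the spread between these arrays, which may be technical. Those of camera at its preset correlation compare the genes of a list with other genes. They rest mainly on the number of genes and do not measure replication. All values are log2 ratios of azacytidine over DMSO, mean ± SD with n = 2 arrays at each time. The SD is between arrays and does not cover differences between features of one gene, and of the 44 named genes with several features 24 had features over 1 apart on the log2 scale at one time or both. Their direction rests on the dyes that the labels name, and their base on the scanner software's convention.

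After 24 h the genes with the highest ratios were PIP, which encodes a secreted protein induced by prolactin and androgen, at 8.02 ± 0.59, and LGALS3, which encodes the lectin galectin-3, at 7.64 ± 0.10. Next came the X-linked homeobox gene RHOXF2B at 6.91 ± 0.61, TSPYL5 at 6.11 ± 0.02, the germ-cell cyclin CCNA1 at 6.10 ± 0.48, TRIM43 at 6.08 ± 0.48, and XIST, the non-coding RNA of X inactivation, at 6.07 ± 0.47. The matrix metalloproteinase MMP7 stood at 5.85 ± 0.44, CEP15 at 5.84 ± 0.04 and the lipocalin LCN2 at 5.84 ± 0.33. GSTP1, a glutathione transferase whose promoter is commonly methylated in prostate cancer, rose by 4.01 ± 0.24 (limma adjusted p = 0.0199), or 16.1-fold. Lowest were the zinc finger gene ZNF417 at -4.51 ± 0.011, the linker histone gene H1-5 at -4.46 ± 0.36, the kainate receptor gene GRIK1 at -4.24 ± 0.12, the metalloproteinase gene MMP26 at -4.09 ± 0.82 and the protease gene TLL1 at -3.79 ± 0.20. LPAL2 stood at -3.65 ± 0.44, LOC105379426 at -3.29 ± 0.11, ANKRD20A12P at -3.12 ± 0.38, SLC22A10 at -3.11 ± 0.048 and LINC02724 at -3.09 ± 1.17. DNMT1, the maintenance DNA methyltransferase that the drug traps, was lower at -0.62 ± 0.057 (limma adjusted p = 0.0192). Both arrays had one sign for each of these genes, and each passed the limma test at an adjusted p threshold of 0.05.

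In all, 4446 of 18334 genes passed that threshold at 24 h, 2618 higher and 1828 lower, and 1482 of the higher and 647 of the lower differed at least 2-fold. Without 24 h replicate 1 limma called 0 genes (3796 at an unadjusted p under 0.05), and without 24 h replicate 2 it also called 0 (3602 at an unadjusted p under 0.05), since the spread, pooled over both times, then came from the 48 h arrays alone. Limma called 7558 with the arrays scaled to one spread and 0 with a term for the replicate number (6503 at an unadjusted p under 0.05), a term that also left 0 genes at 48 h (8152), in the average (7236) and in the difference (7063).

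Germline genes had the highest median of the lists that rose at 24 h. In the list of cancer-testis and germline genes, which are normally expressed in testis, 22 of 40 measured members were higher and 2 lower (25 and 2 adjusted over the list alone). Their median was 1.66 (camera adjusted p = 7.59e-07, adjusted p = 0.347 with an estimated correlation), as log2 ratios throughout. Among them were MAEL, a factor of transposon silencing in germ cells, at 5.76 ± 0.11, the meiotic chromosome axis gene SYCP3 at 4.87 ± 0.20, SPANXA1 at 4.59 ± 0.15 and SSX1 at 3.53 ± 0.046. Of genes with promoters known to be methylated in prostate cancer, 12 of 38 measured members were higher and 0 lower (17 and 0 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 0.00102, adjusted p = 0.347 with an estimated correlation), with CD44 at 5.11 ± 0.25 (features from -0.08 to 6.55), GADD45B at 1.54 ± 0.095 and PDLIM4 at 1.38 ± 0.035. Of interferon-stimulated genes, 21 of 37 measured members were higher and 0 lower (26 and 0 adjusted over the list alone). Their median was 1.20 (camera adjusted p = 8.24e-08, adjusted p = 0.349 with an estimated correlation), with IFI27 at 2.87 ± 0.20, the RNA sensor gene IFIH1 at 1.29 ± 0.085 and IFI6 at 1.20 ± 0.081, whose features were at -0.09 and 2.48. Of antigen presentation genes, 9 of 19 measured members were higher and 0 lower (11 and 0 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 4.99e-04, adjusted p = 0.349 with an estimated correlation). The immunoproteasome subunit gene PSMB9 was at 3.46 ± 0.10 and HLA-G at 0.84 ± 0.002.

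Several other lists rose as well at 24 h. Of p53 targets, 15 of 31 measured members were higher and 1 lower (23 and 2 adjusted over the list alone). Their median was 1.00 (camera adjusted p = 1.71e-06, adjusted p = 0.347 with an estimated correlation). The cell-cycle inhibitor gene CDKN1A was at 2.47 ± 0.12, TP53I3 at 2.34 ± 0.15 and TRIM22 at 3.02 ± 0.089, while SESN1 was lower at -0.86 ± 0.056. Of immediate early genes, 13 of 23 measured members were higher and 1 lower (14 and 1 adjusted over the list alone). Their median was 0.59 (camera adjusted p = 6.64e-04, adjusted p = 0.349 with an estimated correlation), with EGR1 at 2.52 ± 0.042, IER3 at 3.63 ± 0.31 and KLF4 at 2.84 ± 0.045. Of hypoxia and glycolysis genes, 10 of 27 measured members were higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 0.50 (camera adjusted p = 6.64e-04, adjusted p = 0.347 with an estimated correlation), with the peptide hormone gene ADM at 2.83 ± 0.11 and the carbonic anhydrase gene CA12 at 2.69 ± 0.049. Of metallothioneins, 4 of 10 measured members were higher and 0 lower (8 and 0 adjusted over the list alone). Their median was 0.76 (camera adjusted p = 0.00215, adjusted p = 0.365 with an estimated correlation), with MT1M at 3.60 ± 0.046. Of androgen response genes, 14 of 36 measured members were higher and 2 lower (17 and 4 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.0112, adjusted p = 0.347 with an estimated correlation). KLK2, a kallikrein of the prostate, was at 1.52 ± 0.078 with features from 0 to 2.41, ELL2 at 1.82 ± 0.12, and KLK3, which encodes prostate-specific antigen, at 1.17 ± 0.066, although the 3 KLK3 features ranged from -0.39 to 2.28. Of basal epithelial markers, 5 of 11 measured members were higher and 0 lower (5 and 1 adjusted over the list alone). Their median was 0.45 (camera adjusted p = 0.0278, adjusted p = 0.349 with an estimated correlation), with the laminin gene LAMB3 at 3.69 ± 0.18 and the keratin gene KRT15 at 2.04 ± 0.20. The basal median was 0.96 without 24 h replicate 1, 0.94 without genes at 0 on all arrays and 1.42 without features at 0.

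Cell division genes fell at 24 h. In the list of G2/M and mitosis genes, 0 of 36 measured members were higher and 28 lower (1 and 31 adjusted over the list alone). Their median was -1.56 (camera adjusted p = 1.83e-14, adjusted p = 0.347 with an estimated correlation), with the survivin gene BIRC5 at -1.87 ± 0.004, the kinetochore gene CENPF at -2.68 ± 0.13, CDCA3 at -1.95 ± 0.072 and the proliferation marker MKI67 at -2.01 ± 0.091. Of DNA replication and S phase genes, 1 of 37 measured members were higher and 8 lower (2 and 13 adjusted over the list alone). Their median was -0.53 (camera adjusted p = 0.00125, adjusted p = 0.349 with an estimated correlation), with thymidine kinase TK1 at -1.78 ± 0.10 and DTL at -1.68 ± 0.18. Of the DNA methylation machinery, 2 of 17 measured members were higher and 8 lower (3 and 9 adjusted over the list alone). Their median was -0.42 (camera adjusted p = 0.00702, adjusted p = 0.347 with an estimated correlation). The dioxygenase gene TET1 was at -2.23 ± 0.20 and the chromatin remodeller gene HELLS at -1.19 ± 0.18, while DNMT3L, a germline cofactor of de novo methylation, was higher at 1.88 ± 0.21.

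The remaining lists did not pass the camera test at 24 h. They were the integrated stress and unfolded protein response (11 higher and 2 lower of 29, adjusted p = 0.0505), histone genes (2 higher and 2 lower of 16, adjusted p = 0.0603), imprinted genes (5 higher and 3 lower of 25, adjusted p = 0.38), cholesterol synthesis (3 higher and 1 lower of 20, adjusted p = 0.33) and ribosome biogenesis (3 higher and 0 lower of 30, adjusted p = 0.536). The same was found for neuroendocrine markers (3 higher and 0 lower of 16, adjusted p = 0.757), stromal and mesenchymal markers (4 higher and 0 lower of 20, adjusted p = 0.277) and leukocyte and endothelial markers (4 higher and 0 lower of 19, adjusted p = 0.174). Adjusted over the list alone, the counts of higher and lower members were 11 and 2 for integrated stress, 9 and 2 for histone genes and 8 and 5 for imprinted genes. They were 4 and 2 for cholesterol synthesis, 1 and 0 for ribosome biogenesis, 6 and 4 for neuroendocrine markers, and 4 and 0 for each of the other marker lists. Without 24 h replicate 2 the integrated stress list passed (camera adjusted p = 0.034, range over the settings 0.0266 to 0.108), and without either 48 h array histone genes did (0.0412, range 0.0412 to 0.108). The median of features brought past the threshold both the integrated stress list (0.0266) and histone genes (0.044), and the former passed with accessions averaged first (0.0423), without features at 0 (0.0498) and without genes at 0 on all arrays (0.0448). Single members of these lists passed the limma test, among them the neuronal hydrolase gene UCHL1 at 3.47 ± 0.11, the imprinted gene NNAT at 3.13 ± 0.046, CSF1R at 3.25 ± 0.26 and VIM at 2.05 ± 0.13. Camera called 13 of 21 lists at 24 h with its preset correlation of 0.01 and 0 with an estimated correlation (1 at an unadjusted p under 0.05). With an estimated correlation it has only the 2 residual degrees of freedom of the fit. Its 0 calls at any time thus cannot tell whether correlation between genes undoes the lists. The fry test, which asks whether the genes of a list move one way on balance without a comparison with other genes, called 19 lists.

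**Figure D1:**
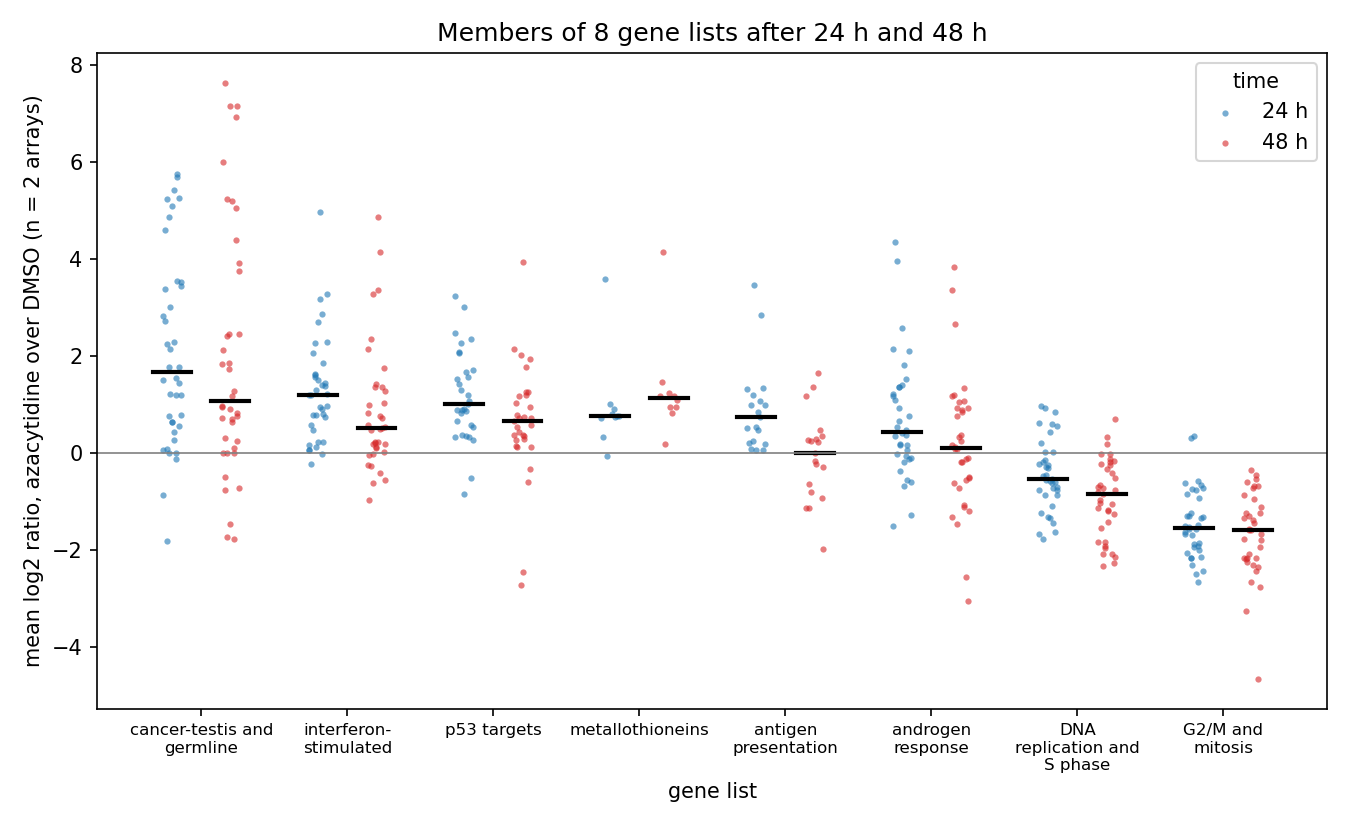
Mean log2 ratio of azacytidine over DMSO (n = 2 arrays) for each measured member of 8 gene lists at 24 h (blue) and 48 h (red), with black bars at the medians. The G2/M and mitosis medians lie at -1.56 and -1.59, and the cancer-testis and germline medians at 1.66 and 1.06.

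After 48 h PIP at 9.60 ± 0.14, LGALS3 at 9.46 ± 0.38 and XIST at 8.12 ± 0.27 had the highest ratios. TKTL1, a transketolase-like gene, followed at 7.63 ± 0.51, then the X-linked cancer-testis genes PAGE2 at 7.16 ± 0.54, PAGE5 at 7.15 ± 0.59 and PAGE2B at 6.99 ± 0.33, TRIM43 at 7.12 ± 0.20, RHOXF2B at 7.08 ± 0.40 and MAEL at 6.93 ± 0.21. GSTP1 was at 6.07 ± 0.66. The lowest ratios were those of the thrombin receptor gene F2R at -4.86 ± 1.19, the phosphatase gene PTPRR at -4.76 ± 1.07 and MKI67 at -4.67 ± 0.56. Next were the ion channel gene TMEM38B at -4.15 ± 0.83, the Mediator subunit gene MED18 at -4.12 ± 0.33, the disaccharidase gene SI at -4.03 ± 0.87, the mitotic kinase gene PBK at -4.01 ± 0.84, the splicing factor gene SF3B4 at -3.97 ± 0.30, ANKRD36BP1 at -3.93 ± 0.28 and the opioid receptor gene OPRK1 at -3.78 ± 0.22. DNMT1 was at -0.68 ± 0.053 (limma adjusted p = 0.0116). CDKN1A was at 0.37 ± 0.53 and did not pass the test (limma adjusted p = 0.309). On 48 h replicate 2 alone its value was -0.0049. Of its 11 features, 10 of one accession lay between 0.15 and 0.27 and the remaining one was at 1.79, and with accessions averaged first, a setting chosen after the data were seen, CDKN1A was at 1.01 and passed (limma adjusted p = 0.0217, range over the settings 0.0217 to 1).

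At 48 h 7116 genes passed the threshold, 3329 higher and 3787 lower, and 1922 of the higher and 2091 of the lower differed at least 2-fold. These calls rest on the narrower spread of the 24 h arrays. From the 48 h arrays alone limma called 0 genes, with a lowest adjusted p of 0.0929 and 6313 genes at an unadjusted p under 0.05, and the same 0 and 6313 were found without 24 h replicate 1 and without 24 h replicate 2.

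The groups that rose at 48 h again included germline genes. In the list of cancer-testis and germline genes 20 of 40 measured members were higher and 4 lower (20 and 4 adjusted over the list alone). Their median was 1.06 (camera adjusted p = 7.36e-05, adjusted p = 0.486 with an estimated correlation), with SSX1 at 3.75 ± 0.35 and SYCP3 at 5.23 ± 0.21. Of p53 targets, 15 of 31 measured members were higher and 2 lower (15 and 2 adjusted over the list alone). Their median was 0.64 (camera adjusted p = 3.69e-04, adjusted p = 0.486 with an estimated correlation), with TRIM22 at 3.94 ± 0.027, and SESN1 lower at -2.47 ± 0.17. Of metallothioneins, 9 of 10 measured members were higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 1.13 (camera adjusted p = 3.66e-04, adjusted p = 0.486 with an estimated correlation), with MT1M at 4.15 ± 0.023 and MT3 at 1.47 ± 0.079. Of interferon-stimulated genes, 14 of 37 measured members were higher and 1 lower (14 and 2 adjusted over the list alone). Their median was 0.51 (camera adjusted p = 0.00239, adjusted p = 0.499 with an estimated correlation), with IFI27 at 4.13 ± 0.26 and IFITM1 at 1.35 ± 0.057. Of immediate early genes, 11 of 23 measured members were higher and 3 lower (12 and 4 adjusted over the list alone). Their median was 0.85 (camera adjusted p = 0.0114, adjusted p = 0.489 with an estimated correlation), with IER3 at 4.12 ± 0.021. Of promoter-methylated genes, 12 of 38 measured members were higher and 4 lower (13 and 5 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.0154, adjusted p = 0.486 with an estimated correlation), with CD44 at 5.22 ± 0.30. Of basal epithelial markers, 6 of 11 measured members were higher and 1 lower (7 and 1 adjusted over the list alone). Their median was 0.61 (camera adjusted p = 0.0173, adjusted p = 0.486 with an estimated correlation), with LAMB3 at 4.74 ± 0.41 and KRT15 at 3.51 ± 0.17. Without 48 h replicate 1 the calls of 4 lists ended, with camera adjusted p = 0.0956 for interferon-stimulated genes, 0.0956 for promoter-methylated genes, 0.0572 for immediate early genes and 0.0572 for basal epithelial markers. Over all settings the lowest values for these lists, in that order, were 3.0e-04, 0.0047, 0.0022 and 0.0099, and the values without that array were the highest. The median of interferon-stimulated genes was then 0.24, with 11 members higher and 5 lower, and that of p53 targets 0.42, with 10 higher and 5 lower (camera adjusted p = 0.04996). Without features at 0 the 48 h median was 1.78 for cancer-testis genes, 0.88 for promoter-methylated genes and 1.34 for basal markers, which stood at 0.97 without genes at 0 on all arrays.

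Cell division genes were lower at 48 h too. In the list of G2/M and mitosis genes 0 of 36 measured members were higher and 33 lower (0 and 34 adjusted over the list alone). Their median was -1.59 (camera adjusted p = 2.26e-12, adjusted p = 0.486 with an estimated correlation), with BIRC5 at -2.36 ± 0.038, DLGAP5 at -2.25 ± 0.08 and CENPF at -2.17 ± 0.04. Of DNA replication and S phase genes, 1 of 37 measured members were higher and 17 lower (1 and 25 adjusted over the list alone). Their median was -0.86 (camera adjusted p = 3.07e-05, adjusted p = 0.486 with an estimated correlation), with the origin recognition gene ORC1 at -1.85 ± 0.081 and the primase gene PRIM1 at -1.06 ± 0.018. These were the only lists of the 21 that camera called lower at 48 h. On the same arrays 193 genes for ribosomal proteins, the proteasome, the respiratory chain, the ATP synthase and translation initiation factor 3 had a median of -0.64, against 0.13 at 24 h. GAPDH, looked at after the data were seen, was at -1.63 ± 0.67 (limma adjusted p = 0.0419) against -0.12 ± 0.13 at 24 h, a difference of -1.51 that did not pass the test (limma adjusted p = 0.0926). Of the 13 ACTB features, which share one accession, 10 lay between 0.026 and 0.13 at 48 h and 1 at 1.09, while the remaining features were at -2.33 and -1.85, after 1.14 and 0.61 at 24 h.

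No other list passed the camera test at 48 h. The counts were 11 higher and 8 lower of 36 androgen response genes (adjusted p = 0.557), 3 higher and 5 lower of 19 antigen presentation genes (adjusted p = 0.896), 1 higher and 7 lower of 17 genes of the DNA methylation machinery (adjusted p = 0.423), 7 higher and 9 lower of 29 integrated stress and unfolded protein response genes (adjusted p = 0.459) and 8 higher and 5 lower of 27 hypoxia and glycolysis genes (adjusted p = 0.219). They were 5 higher and 4 lower of 25 imprinted genes (adjusted p = 0.601), 2 higher and 3 lower of 20 cholesterol synthesis genes (adjusted p = 0.193), 6 higher and 8 lower of 30 ribosome biogenesis genes (adjusted p = 0.373) and 3 higher and 4 lower of 16 histone genes (adjusted p = 0.833), whose median of -0.13 and camera direction, up, differ in sign. For markers of other cell types they were 5 higher and 3 lower of 16 neuroendocrine markers (adjusted p = 0.193), 5 higher and 2 lower of 20 stromal and mesenchymal markers (adjusted p = 0.127) and 6 higher and 1 lower of 19 leukocyte and endothelial markers (adjusted p = 0.128). Members that passed the limma test included KLK2 at 1.34 ± 0.11 with features from 0 to 2.88, KLK3 at 1.16 ± 0.058 with features from -0.12 to 3.03, ADM at 4.08 ± 0.072, CHAC1, an enzyme of glutathione breakdown, at 1.88 ± 0.23, TET1 at -2.64 ± 0.026, the cholesterol synthesis genes NSDHL at -2.13 ± 0.012 and SQLE at 1.59 ± 0.30, and the decarboxylase gene DDC at -3.28 ± 0.81. Stromal and mesenchymal markers passed without 48 h replicate 2 (camera adjusted p = 0.0339, range over the settings 0.0339 to 0.261). Camera called 9 of 21 lists at 48 h with its preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 16.

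**Figure D2:**
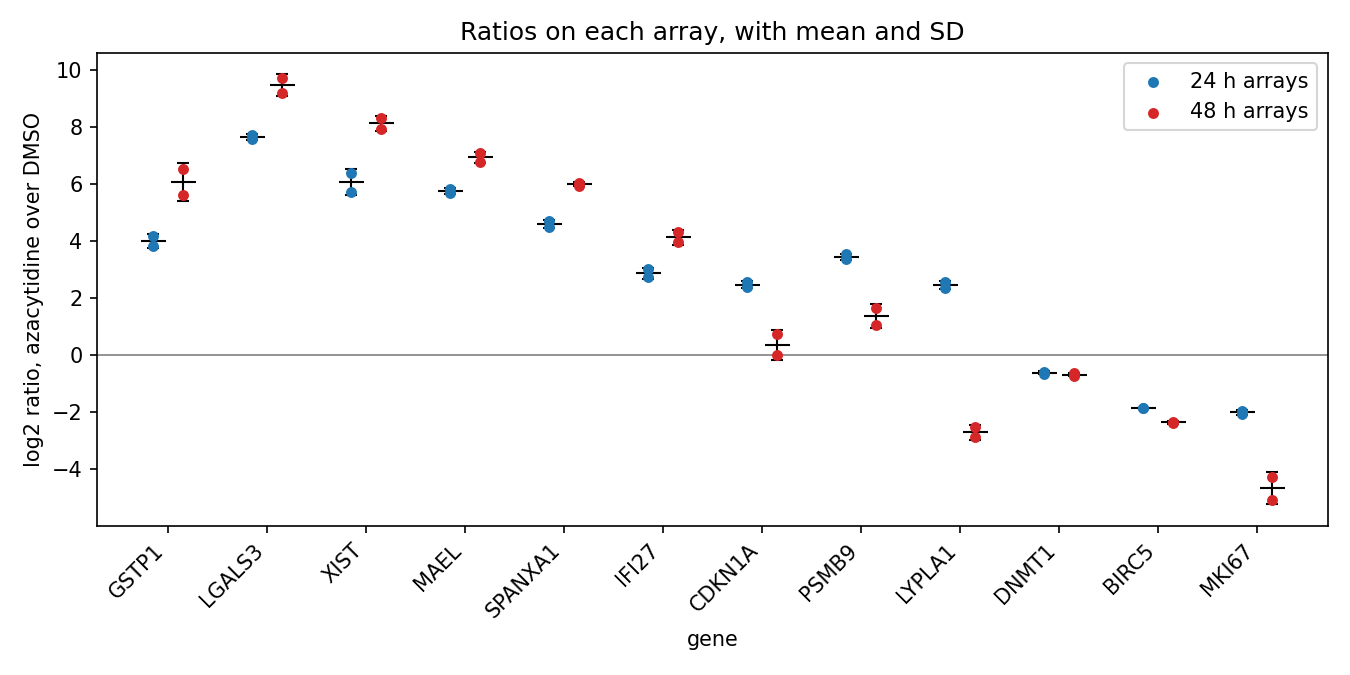
Log2 ratio of azacytidine over DMSO on each array for 12 genes at 24 h (blue) and 48 h (red), with the mean and SD of 2 arrays in black. GSTP1 goes from 4.01 to 6.07 and LYPLA1 from 2.46 to -2.71.

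Averaged over both times, germline, interferon and p53 target genes were higher and cell division genes lower. Of cancer-testis and germline genes, 22 of 40 measured members were higher and 1 lower (23 and 1 adjusted over the list alone). Their median was 1.40 (camera adjusted p = 2.55e-07, adjusted p = 0.27 with an estimated correlation). Of interferon-stimulated genes, 23 of 37 measured members were higher and 0 lower (28 and 0 adjusted over the list alone). Their median was 0.83 (camera adjusted p = 7.34e-09, adjusted p = 0.27 with an estimated correlation). Of p53 targets, 19 of 31 measured members were higher and 1 lower (24 and 2 adjusted over the list alone). Their median was 0.89 (camera adjusted p = 1.34e-07, adjusted p = 0.27 with an estimated correlation). Of G2/M and mitosis genes, 0 of 36 measured members were higher and 34 lower (0 and 34 adjusted over the list alone). Their median was -1.56 (camera adjusted p = 5.67e-15, adjusted p = 0.27 with an estimated correlation). Of DNA replication genes, 0 of 37 measured members were higher and 20 lower (0 and 23 adjusted over the list alone). Their median was -0.58 (camera adjusted p = 4.70e-07, adjusted p = 0.27 with an estimated correlation). Camera called 16 of the 21 lists in the average, 13 higher and 3 lower. Among them were stromal and mesenchymal markers (6 higher and 1 lower of 20) and leukocyte and endothelial markers (6 higher and 0 lower of 19), with adjusted p = 0.0312 and 0.0398, and adjusted p = 0.327 and 0.27 with an estimated correlation. Stromal markers did not pass without 24 h replicate 2 (adjusted p = 0.0651, range 0.0164 to 0.0651), nor did leukocyte markers (0.0504, range 0.0185 to 0.0504) or, without 48 h replicate 2, leukocyte markers (0.0503). The medians of these lists, 0.30 and 0.17, were 0.55 and 0.54 without features at 0, and the stromal median was 0.19 with accessions averaged first. Androgen response (16 higher and 8 lower of 36, adjusted p = 0.0398, adjusted p = 0.27 with an estimated correlation, range 0.0292 to 0.094) did not pass without 24 h replicate 1 (0.0565), 48 h replicate 1 (0.094) or 48 h replicate 2 (0.0621), nor with the median of features (0.0516) or without features at 0 (0.0639). The integrated stress response (9 higher and 3 lower of 29, adjusted p = 0.0376, adjusted p = 0.531 with an estimated correlation, range 0.0201 to 0.135) did not pass without 24 h replicate 1 (0.0585) or 48 h replicate 1 (0.135). Nor did it pass with scaling (0.124), with quantile normalization (0.102), without features at 0 (0.0813) or without genes at 0 on all arrays (0.0716). The DNA methylation machinery (2 higher and 9 lower of 17, adjusted p = 0.0105, adjusted p = 0.27 with an estimated correlation, range 0.0071 to 0.0791) did not pass without 48 h replicate 1 (0.0791), and histone genes (5 higher and 1 lower of 16, adjusted p = 0.113, range 0.0227 to 0.331) passed without 48 h replicate 2 (0.0227). With an estimated correlation camera called 0 lists in the average, the lowest adjusted p being 0.27 (1 list at an unadjusted p under 0.05), and fry called 18.

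In the average 6029 genes passed the threshold, 3057 higher and 2972 lower, and 1503 of the higher and 619 of the lower differed at least 2-fold. Which direction held more calls turned with the setting, with 3493 higher and 3719 lower after scaling, 3466 and 3766 after quantile normalization, 3441 and 3795 without features at 0, and 3452 and 3579 without genes at 0 on all arrays. It also turned without 48 h replicate 1 (3394 and 4191), without 48 h replicate 2 (2952 and 3231) and with features in place of genes (4943 and 5388). Genes called at both times comprised 1356 higher at both, 736 lower at both and 810 called in opposite directions. Calls at the times share each gene's variance and the dye orientation, so these overlaps have no plain chance level. Mean ratios at the 2 times correlated with r = 0.428 across genes. Without 24 h replicate 1 limma called 0 genes in the average (5206 at an unadjusted p under 0.05), and without 24 h replicate 2 also 0 (5124 at an unadjusted p under 0.05). All 4 arrays carried treated RNA in one dye, so a dye bias cannot be separated from treatment in the values at one time or in their average, whereas a constant bias cancels in the difference between times.

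The difference between 48 h and 24 h was largest, among genes whose arrays did not overlap, for LINC03156 at 6.66, the calcium-binding protein gene CABP7 at 6.15, LOC100506124 at 4.18, the potassium channel gene KCNG4 at 3.44 and CFAP53 at 3.18. Each of these had a mean below 0 at 24 h and above 0 at 48 h, but none passed the threshold at both times. LINC03156 (3.26 ± 1.59 at 48 h) and CABP7 (2.78 ± 1.65 at 48 h) passed at neither time. LOC100506124 passed only at 24 h, and KCNG4 and CFAP53 only at 48 h. On the other side were ANKRD36BP1 at -5.46, the thioesterase gene LYPLA1 at -5.16, SF3B4 at -4.79, the cholesterol synthesis gene MSMO1 at -4.70 and the lysosomal membrane gene LAPTM4B at -4.53. LYPLA1 went from 2.46 ± 0.15 at 24 h to -2.71 ± 0.26 at 48 h (limma adjusted p = 0.0213 for the difference). CDKN1A had a difference of -2.10 (limma adjusted p = 0.048) and MKI67 one of -2.66 (limma adjusted p = 0.0415). The differences of GSTP1, 2.06 (limma adjusted p = 0.0635), and DNMT1, -0.06 (limma adjusted p = 0.522), did not pass the test.

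The difference passed the threshold for 4211 genes, 1802 higher at 48 h and 2409 lower, and 1000 of the higher and 1785 of the lower differed at least 2-fold. The excess of lower calls was smaller after scaling, with 3095 higher and 3432 lower, and absent after quantile normalization, with 3465 higher and 3401 lower. No list passed the camera test of the difference. At an unadjusted p under 0.05 it called 3. The lowest adjusted p was that of antigen presentation, 0.065, with a median difference of -0.98, 7 of 19 members lower and 1 higher. It passed without 24 h replicate 2 (0.0216, range over the settings 0.0216 to 0.27), with scaling (0.0377), with quantile normalization (0.0478) and without genes at 0 on all arrays (0.048). With an estimated correlation camera also called 0 lists (0 at an unadjusted p under 0.05), and fry called 4. At 48 h the ratios of 193 genes for cytosolic ribosomal proteins, the proteasome, respiratory chain subunits, the ATP synthase and translation initiation factor 3 differed from those at 24 h by a median of -0.83 (-0.54 without 48 h replicate 2). The ratios of 50 olfactory receptor genes with a value other than 0 on all arrays differed by a median of 0.32 (0.50 without 48 h replicate 2). Without 24 h replicate 1 limma called 0 genes in the difference (3809 at an unadjusted p under 0.05), and without 24 h replicate 2 also 0 (3821). Without 48 h replicate 1 it called 7786 genes.

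**Figure D3:**
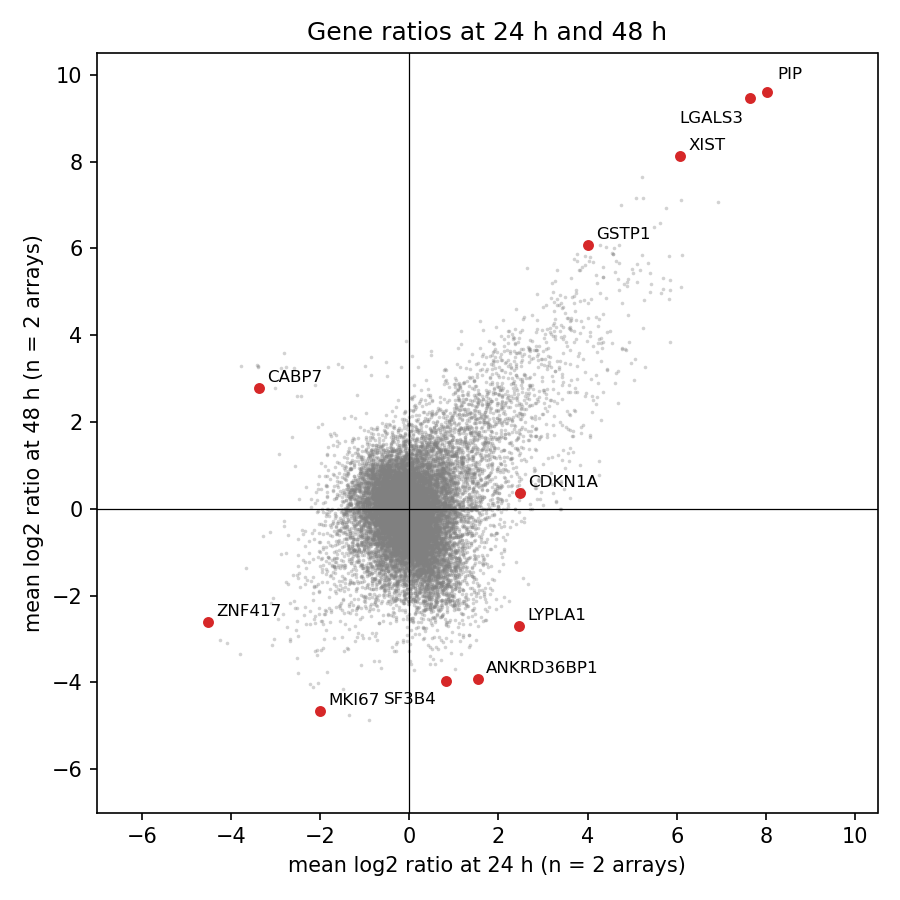
Mean log2 ratio of azacytidine over DMSO at 24 h (horizontal axis) and at 48 h (vertical axis) for 18334 genes (grey points, n = 2 arrays per time), with 11 named genes in red. PIP, LGALS3, XIST and GSTP1 lie high at both times, and LYPLA1, SF3B4 and ANKRD36BP1 lie above 0 at 24 h and below 0 at 48 h.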

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

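The tests of array spread, of 48 h replicate 2 and of dye bias were chosen after the results were seen, while the olfactory receptor test was planned before its result was seen; it was first run with a stricter rule, and the constitutive genes with further sets, and both were put back to the plan after their first values had been seen.

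A test of the difference between 48 h and 24 h passed the threshold for 4211 genes, and the values below are the log2 differences, 48 h minus 24 h, of named genes that passed it. Higher at 48 h were LINC03156 (6.66), CABP7 (6.15), LOC100506124 (4.18), KCNG4 (3.44), CFAP53 (3.18), LOC105379426 (2.66), XIST (2.05), ZNF417 (1.89), LGALS3 (1.82), KRT15 (1.47), SPANXA1 (1.41), IFI27 (1.27), ADM (1.25), MAEL (1.18), MT3 (1.15), CHAC1 (1.15), HK2 (1.096), PDLIM4 (1.04), SLC22A10 (0.95), TRIM22 (0.92), H1-2 (0.82), PSMB10 (0.65), CDCA3 (0.57), MT1M (0.55), IFITM1 (0.55), H2AC8 (0.47), IER2 (0.46) and EIF4EBP1 (0.46). Lower at 48 h were ANKRD36BP1 (-5.46), LYPLA1 (-5.16), SF3B4 (-4.79), MSMO1 (-4.70), LAPTM4B (-4.53), NSDHL (-2.93), MKI67 (-2.66), CDKN1A (-2.10), PSMB9 (-2.09), DIRAS3 (-1.74), SESN1 (-1.60), ORC1 (-1.55), LUM (-1.36), OPRK1 (-1.28), FN1 (-1.25), KLF4 (-1.16), PRIM1 (-1.06), ELL2 (-0.98), VWF (-0.85), MKRN3 (-0.79), COL3A1 (-0.75), DLGAP5 (-0.67), IFI6 (-0.62), MRTO4 (-0.53), BIRC5 (-0.49) and FBL (-0.45). DIRAS3 was listed at 0 on 1 of the 48 h arrays. By limma the difference passed for 0 genes without 24 h replicate 1 (3809 at an unadjusted p under 0.05) and for 0 without 24 h replicate 2 (3821), and without 48 h replicate 1 for 7786.

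Features that the gene analysis left out also passed the threshold. Of 12044 features without a single gene symbol, 2169 passed the threshold in the average over both times, 820 higher and 1349 lower, which is 18.01% against 26.1% of the features with one symbol.

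Constitutive genes were lower at 48 h than at 24 h, with a median difference of -0.83 over 193 genes of 6 sets, 151 of them below 0, 38 past the threshold lower and 10 higher. The sets were taken by gene symbol, so not every member is constitutive. Members include the antigen presentation genes PSMB9 (-2.09, past the threshold lower) and PSMB10 (0.65, past it higher). The median over all members was -0.70 after scaling and -0.68 after quantile normalization. Scaling leaves the sign of every ratio unchanged, while the set median was 0.13 at 24 h and -0.64 at 48 h. A difference near 0 was thus hardly possible, so scaling does not decide on the wider spread of the 48 h arrays. Over all members, the median of -0.54 without 48 h replicate 2 argues against that array alone (bootstrap interval -0.74 to -0.32). Without 48 h replicate 1 it was -1.12, so the shift was larger on replicate 2. Bootstrap intervals here resample the genes of a set and do not measure the spread between arrays. Without 48 h replicate 2 the median was -0.66 over 142 members of 4 sets. By set it was -0.94 for the proteasome, -0.72 for ribosomal proteins, -0.48 for the ATP synthase and -0.25 for translation initiation factor 3. It was -0.083 (bootstrap interval -0.56 to 0.18) over the 51 members of respiratory complex I and cytochrome c oxidase, 4 of them past the threshold lower and 5 higher with all arrays. For these last sets, singled out after their values were seen, 48 h replicate 2 stays open as the cause. Genomic DNA or unspliced RNA in the treated 48 h RNA also remains a candidate explanation. The planned test used 50 olfactory receptor genes with a value other than 0 on all arrays. Such genes are silent in most tissues and mostly without introns in their coding part. They differed by a median of 0.32 (16 of 50 below 0, 7 past the threshold higher and 3 lower), over the planned level of 0.25. Their bootstrap interval of 0.16 to 0.68 reaches below that level, and by the stricter rule on the whole interval the test is undecided. A rise of silent genes through the treatment itself could move them likewise, so the test cannot tell it from such DNA or RNA. A lower share of the constitutive transcripts in cells treated for 48 h stays open untested, as does RNA quality. The parting of ACTB features at 48 h (-2.33 and -1.85, against 0.026 to 0.13 for 10 others and 1.09 for another) may be a sign of the latter. The features at -2.33 and -1.85 lay apart the other way at 24 h, at 1.14 and 0.61, so their parting is not particular to 48 h.

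The changes of G2/M and of cancer-testis genes at both times were measured with treated RNA always in one dye. Of the 57 members called in the average, 14 passed the test of the difference between times with the arrays of the 2 times apart, much as 4211 of all 18334 genes passed it, and a constant dye bias as the whole cause would give no such difference in these 14. They are known only by that test, which passed for 0 genes by limma without either 24 h array (3809 and 3821 at an unadjusted p under 0.05), so the argument is no stronger than the test. The argument also covers only a bias of one size at both times. Gene ratios spread wider at 48 h (median absolute deviation 0.68 and 0.98, against 0.59 and 0.62 at 24 h). A bias that grew with that spread stays open for the 14, which were not counted again after scaling. For the 43 members that did not pass the test of the difference, dye bias and treatment cannot be told apart, since no array had the dyes exchanged.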

How the results depend on the processing

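Counts of genes are given for 24 h, 48 h, the average and the difference in that order, against 4446, 7116, 6029 and 4211. The averaging by accession and the removal of genes at 0 on all arrays, alone and with an array left out, were chosen after seeing the data. Leaving out each array in turn gave counts from 0 to 6655 at 24 h, 0 to 8303 at 48 h, 0 to 7585 in the average and 0 to 7786 in the difference. All 4 counts were 0 without 24 h replicate 1 and without 24 h replicate 2, where the spread came from the 48 h arrays only (between 3602 and 6313 genes at an unadjusted p under 0.05 by limma). Without genes at 0 on all arrays, leaving out either 24 h array still gave 0 in all 4 (3264 to 7017 at an unadjusted p under 0.05), while leaving out either 48 h array gave 8107 at 24 h and leaving out 48 h replicate 1 gave 9466 at 48 h, 8741 in the average and 9106 in the difference. The same removal with all arrays gave 6884 in the difference. From the 48 h arrays alone 0 genes passed at 48 h. With a replicate block limma called 0, 0, 0 and 0 genes (6503, 8152, 7236 and 7063 at an unadjusted p under 0.05) and the same numbers of lists. The labels do not say that replicate numbers pair the arrays, and the deviations of same-numbered arrays correlated with r = -0.035, so the block costs a degree of freedom without a known pairing. Scaling gave 7558 at 24 h and 6527 in the difference, and quantile normalization 7443 and 6866. Without features at 0 the difference had 7361 genes, and with robust moderation 2609. Features in place of genes gave 7726, 13337, 10331 and 8175 of 43376. A 2-fold threshold left 2129, 4013, 2122 and 2785, of which 69.6% at 24 h and 70.8% in the average were higher, against 58.9% and 50.7% of all calls. With the values read as log2, 210 genes in the average passed with a size of at least 1, 97.1% of them higher. Centring moved nothing, since the medians were 0. The remaining counts stayed within 1.5 times. Removal of genes at 0 on all arrays left the ratios of the other genes unchanged. Its shift thus came from the number of genes tested or from the variance moderation, whose prior degrees of freedom went from 0.735 to 2.40. The causes of the shifts from scaling, features at 0, robust moderation and features in place of genes were not tested.

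Camera's list counts, 13, 9, 16 and 0, were 0 throughout with an estimated correlation, a test with only the 2 residual degrees of freedom of the fit. Fry gave 16 at 48 h and 4 in the difference. Left-out arrays gave 5 to 10 lists at 48 h and 0 to 1 in the difference. Antigen presentation was the 1 list called in the difference with scaling, with quantile normalization and without genes at 0 on all arrays. Of 220 values of named genes under 13 settings, 2142 results kept direction and side of the threshold, 672 lost the threshold, 39 gained it and 5 changed sign. The 5 were PRIM1 at 24 h with the median of features (-0.0008), COL3A1 at 48 h with averaging by accession (-0.057) and without 48 h replicate 1 (-0.0039), and SREBF2 (0.0011) and CDKN1A (-0.0049) at 48 h without that array, none past the threshold. Without 48 h replicate 2 these were 0.064 for COL3A1, -0.12 for SREBF2 and 0.74 for CDKN1A at 48 h. The block and either left-out 24 h array ended the call of 197 of these 220 values. Signal over background was not analysed here, so its limit on weak features is unknown.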

Other observations

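The sets of cleavage-stage and spermatid genes and their tests were chosen after the highest genes had been seen, and the test of cross-hybridization also used genes already seen, whereas the tests on unseen members, on spermatid genes and on neighbouring genes were set before their results were known.

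Genes of the early embryo that the transcription factor DUX4 switches on at the cleavage stage stood out among the highest ratios. All 10 members noticed there were higher past the threshold at both times, with a median average log2 ratio of 5.27, among them ZSCAN4 at 5.48 ± 1.09 at 24 h and 6.49 ± 0.55 at 48 h, LEUTX at 4.42 ± 0.27 and 6.03 ± 0.40, MBD3L2 at 4.12 ± 0.28 and 5.68 ± 0.42, and PRAMEF1 at 4.91 ± 0.023 and 5.30 ± 0.33. These genes were picked for their values, so members that had not been seen were tested, 20 measured of 43 listed. The 20 include PRAMEF8, PRAMEF10 and TRIM64, of families already among the picked genes, and are thus not a fully independent check. Their median average log2 ratio was 2.07, above the 95th percentile of 0.13 for 10000 random lists of that size. Of the 20, 15 were higher at 24 h, 14 at 48 h and 14 at both, and 0 were lower. Among these, named after their values were seen, were KHDC1 at 3.35 ± 0.30 and 3.23 ± 0.047, FAM151A at 3.37 ± 0.01 and 4.93 ± 0.66, KLF17 at 2.52 ± 0.56 and 2.94 ± 0.34, and ALPG at 3.45 ± 0.079 and 3.58 ± 0.17. Without either 24 h array limma called 0 genes at both times (3602 to 6313 at an unadjusted p under 0.05), so these calls too rest on the spread of the 24 h arrays.

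A candidate explanation is a shared induction of the set that DUX4 activates, and the median of 2.07 among unseen members is in line with it. Cross-hybridization within the TRIM and PRAMEF families as the whole cause is argued against by members with 14 other symbol stems that were higher at both times. A rise of all genes silent outside the testis is argued against by 30 spermatid genes, whose median average log2 ratio was 0, although cancer-testis and germline genes, with a median of 1.40 and 22 of 40 higher, go with a rise of part of that class, which stays open. Of the spermatid genes 11 were listed at 0 on all arrays, and the 12 with a ratio on all arrays had a median of 0.0070, against 2.38 for the 18 unseen members with a ratio on all arrays (bootstrap interval of the difference, over genes and not arrays, -2.94 to -1.47). The list was written from general knowledge, several members have other regulators, DUX4 activity was not measured, and a dye bias stays open as for other ratios, so the pattern remains a hypothesis.

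The test set for neighbouring genes did not find more induced pairs than random draws gave. It left out pairs whose symbols begin alike, so gene families that lie together were not tested. Only genes directly next to each other counted, and a small excess cannot be excluded. Of 440 genes higher past the threshold by at least 2 on the log2 scale at both times, 13 pairs with different symbol stems were next to each other among the measured genes, against a mean of 9.38 in 10000 random draws, and a share of 0.152 of draws gave as many.

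In the difference between times, long non-coding RNA genes passed the threshold higher at 48 h more often than protein-coding genes, with 140 of 1063 (13.2%) against 1595 of 16724 (9.54%, 2-sided Fisher's exact test p = 1.86e-04, chosen after the data were seen, over genes that are not independent). Lower at 48 h were 58 of the 1063 and 2298 of the 16724. The median difference of the long non-coding RNA genes was 0.029, and 0 after scaling.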
